A study of Mus musculus with 5 samples.

How the data were processed

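RNA-seq of the mouse forebrain at E12.5 covered 5 samples, 3 labelled EedcKO and 2 labelled wild type, described by the submitters as littermates. Per the labels' protocols, forebrains were frozen, RNA was extracted with Trizol, polyadenylated RNA was used, and libraries followed the BGISEQ-500 procedure. Samples were grouped by their titles and genotype labels. The labels state neither which samples share a litter nor that each came from a separate embryo, so p-values measure the spread between these samples, part of which may be technical.

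Reads were aligned to mm10, and HISAT2 2.2.0 is the tool named, per the submitters' processing notes. About 30000000 reads per sample were mapped, per the labels. The tool that counted reads, its use of strand, the gene annotation and the handling of duplicate reads are not given in the sources used here. The authors deposited a table of whole-number counts per gene, not normalized, with 56196 rows, and a table of TPM (length-scaled transcript abundance) with 24926 rows, in which every column has the same sum. For 18749 genes in both tables, the ratio of deposited count to deposited TPM had the same proportions between genes in every library where they had counts, so the TPM table holds the same counts divided by 1 length per gene. Each count column summed to 16.1% to 16.8% of the stated reads. The highest count was 6396, for Map1b in wild type 1, or 0.130% of that library. The 100 most abundant genes took 5.05% to 5.81% of the counts. Differences between the most abundant genes may therefore be compressed, and how this arose is not given in the sources used here.

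Among the rows with counts, 28277 (50.3%) carried no gene symbol and 2.01% to 2.16% of the counts. They were left out of library sizes and of the tests, and tested apart with the same library sizes. For 407 symbols on several rows, the symbol was given to the row with at least 99% of its counts. The other rows, and 23 symbols that a spreadsheet had turned into dates, were tested but not named. The tables held 0 columns of samples outside the series. The 13 mitochondrially encoded genes that had been listed were not analysed here. Coordinates were taken by symbol from the GENCODE annotation of the mm10 assembly, 1-based.

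Counts were analysed in R 4.3.3 with edgeR 4.0.16. The steps were filterByExpr by group, TMM normalization, glmQLFit with robust estimation and glmQLFTest on the group alone. P-values had Benjamini-Hochberg adjustment over the 13989 genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM are scaled by TMM. On simulated counts for 13848 genes with the spread of these libraries, the edgeR fit found 35.8%, 85.1% and 93.9% of genes changed by 1.5-fold, 2-fold and 4-fold, and 15 of its 158 calls were false. Depth set the precision of low counts: 3 counts, the limit that a count of 0 allows, correspond to 0.610 to 0.632 CPM. Poisson and binomial intervals are at 95% and cover counting error only, since reads carry no molecular identifiers. Library pairs differed by 2.61 to 10.8 times the chi-square that sampling noise gives per gene, so no pair was treated as a duplicate.

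The design, the 37 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were first the PRC2 core, and then the 10 largest increases and 10 largest decreases past the threshold. These needed a mean log2 CPM of at least 1 and no overlap of the groups, and predicted genes were left out. Further named genes were up to 4 members of each list past the threshold with the largest change, or the 2 with the smallest p given as values, and Xist with the Y-linked genes. All 448 genes past the threshold had groups that did not overlap, as had 33.8% of all tested genes, where chance gives 20%. Lists with at least 3 tested members were tested with Fisher's exact test per direction, with camera at a preset correlation of 0.01 and with fry, the latter pair from limma 3.58.1, each adjusted over lists. A few genes belong to 2 lists, such as Zic1 in the Cajal-Retzius and pericyte lists and Fabp7 in the radial glia and neural crest lists.

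Alternatives fixed beforehand were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, robust estimation off, no count filter, a filter at 1 CPM in 2 libraries and a test against a 1.5-fold change. Others were limma-trend on log2 of TPM with pseudocounts of 1 and 0.1 and with no filter on low values, embryo sex as a covariate, the replicate number as a block and globin genes left out. Also fixed were each library left out in turn, camera with an estimated correlation, cameraPR and adjustment over a list alone. Removal of a trend with gene length or GC content from each library, and a fit of the female libraries alone, were added after the data were seen. Fits that left 1 wild-type or 1 EedcKO library assume that it varies like the other group. Some genes that passed the threshold are not reported by name here; they remain in the counts of each list.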

Results

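Polyadenylated RNA of the mouse embryonic forebrain at E12.5 was sequenced from 3 EedcKO and 2 wild-type C57BL/6 littermate samples. Eed encodes a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. EedcKO is the submitters' name for the mutant. Neither the means of deletion nor the deleted part of the gene is given in the sources used here. The comparison asked which transcripts differ in the early forebrain when Eed is deleted. The counts summed to 5026381 in wild type 1 and 4820630 in the library labelled wild type 2. They summed to 4915493, 4959394 and 5008928 in EedcKO 1, 2 and 3. Between 16931 and 17490 named genes had at least 1 count in a library. Fold changes are given as EedcKO over wild type, and each mean of CPM (counts scaled to a common library size) is over 2 wild-type or 3 EedcKO libraries.

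The count of Eed, the targeted gene, went against 1 label. Eed (chromosome 7, 89954654 to 89980983, minus strand, mm10) had 404 counts in wild type 1 (95% Poisson interval 366 to 445) and 238 in the library labelled wild type 2 (209 to 270). EedcKO 1, 2 and 3 had 251, 233 and 247 counts. The same values as CPM were 85.2, 48.4, 52.4, 48.2 and 50.6. The log2 fold change over all 5 libraries was -0.40 (SE 0.22, edgeR adjusted p = 0.412), a difference within the spread between the wild-type libraries. With the library labelled wild type 2 left out it was -0.75 (edgeR adjusted p = 0.00968), and with wild type 1 left out 0.043. A count over the whole gene can include exons outside the deleted part, so it checks the labels only in part. The 39 HOX genes, classical targets of Polycomb repression that the forebrain normally keeps silent, set wild type 1 apart in the same way. They summed to 2 counts in wild type 1 (0.242 to 7.22) and 134 in the library labelled wild type 2 (112 to 159). In EedcKO 1, 2 and 3 they summed to 85, 184 and 62 counts. Xist and Y-linked counts marked both wild-type libraries and EedcKO 1 as female (3127 to 5239 Xist counts, at most 12 Y-linked counts). EedcKO 2 and 3 were male (1670 and 1406 Y-linked counts, at most 4 Xist counts). Because of the Eed count, every direction below is drawn against a wild-type group that includes a library at the EedcKO level of Eed.

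**Figure D1:**
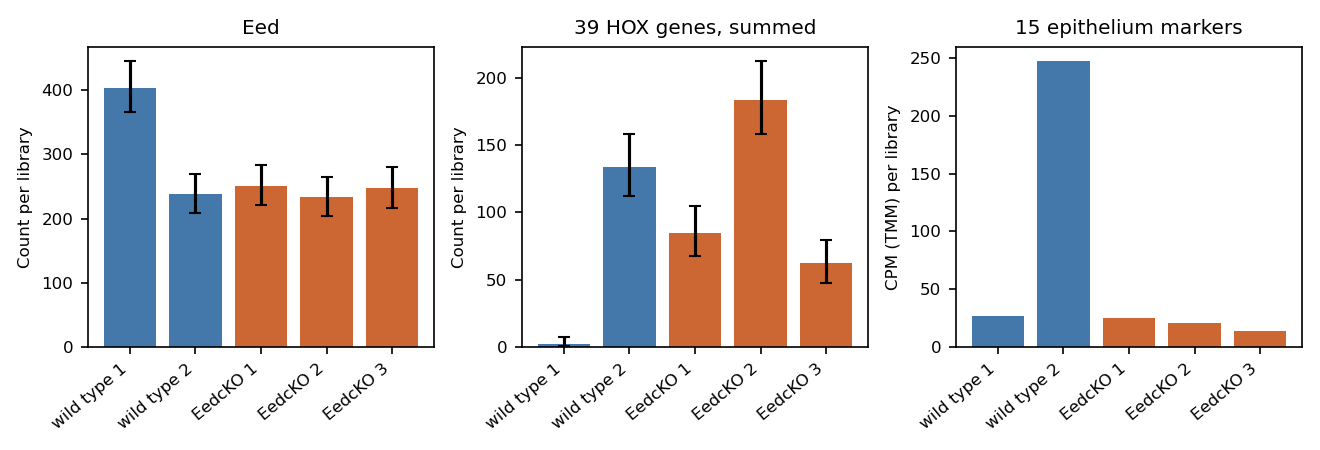
Counts per library of Eed (left) and of 39 HOX genes summed (middle), with 95% Poisson intervals, and CPM of 15 epithelium markers summed (right); blue bars are libraries labelled wild type and orange bars EedcKO. The library labelled wild type 2 had 238 Eed counts and 134 HOX counts, against 404 and 2 in wild type 1, and its epithelium markers reached 247 CPM.

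Of listed genes that mark the ventral telencephalon and the diencephalon, 7 of 25 and 3 of 15 tested passed as lower in EedcKO. Of genes that mark neurogenesis and cortical excitatory neurons, 5 of 16 and 8 of 17 passed as higher. As whole lists none of these passed camera with an estimated correlation (adjusted p = 0.362 for each). Shh, the ventral morphogen, fell from 23.5 ± 3.68 CPM (SD, n = 2) to 0.622 ± 0.419 CPM (SD, n = 3), and Lhx8, a transcription factor of ventral cholinergic neurons, from 76.2 ± 13.5 to 2.78 ± 3.94 CPM. Neurod4, a proneural transcription factor, rose from 5.98 ± 2.19 to 31.8 ± 8.12 CPM, and Slc17a7, a vesicular glutamate transporter, from 22.2 ± 5.72 to 93.0 ± 27.4 CPM. Of 13989 genes tested with edgeR's quasi-likelihood test, 448 passed a false discovery rate of 0.05. Of these 145 were higher and 303 lower in EedcKO, and 211 differed at least 2-fold (52 higher, 159 lower). These directions are drawn with the library labelled wild type 2, whose Eed count went against its label, among the wild type. Without that library 882 genes passed (295 higher, 587 lower). The count was 1012 without wild type 1, 262 without EedcKO 1, 84 without EedcKO 2 and 0 without EedcKO 3. In that last fit 1887 genes had an unadjusted p under 0.05 with edgeR, limma-voom also called 0 genes and DESeq2 called 254. All 448 genes kept their direction in it, each with an unadjusted edgeR p under 0.05, though it shares its libraries with the main fit. The groups did not overlap for any of the 448, so leaving out a library could not reverse a direction. No gene passed with embryo sex as a covariate, where edgeR had 1611 genes at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 55. As no wild type was male, the genotype effect of that fit compares EedcKO 1 alone with the wild type. All 448 genes kept their direction there too, which was fixed in advance, since EedcKO 1 lay beyond both wild-type libraries in each of them.

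The largest decreases among genes with a mean log2 CPM of at least 1 whose groups did not overlap included Otp, a transcription factor of the hypothalamus (chromosome 13, 94875602 to 94885130, mm10). It had 428 counts in wild type 1 and 85 in the library labelled wild type 2 (53.8 ± 51.6 CPM, SD, n = 2), and 0, 1 and 1 in EedcKO 1, 2 and 3. The ratio of the group sums, scaled to library size, was 385-fold with a 95% counting interval of 106 to 3187, which leaves out the spread between the wild-type libraries. The ratio was 125-fold without wild type 1 and 654-fold without the library labelled wild type 2. Shh (chromosome 5, 28456815 to 28467256) had a log2 fold change of -5.19 (SE 0.40, edgeR adjusted p = 0.00455), and Lhx8 (chromosome 3, 154306294 to 154330659) of -4.77 (SE 0.74, edgeR adjusted p = 0.0384). AI606473, which lies beside Lhx8 on chromosome 3 (154330821 to 154334254), had -5.02. Next came Onecut3 (-3.94), Gbx1 (-3.78), the acid-sensing channel family member Asic4 (-3.68) and the nociceptin precursor Pnoc (-3.56). The neural crest and oligodendrocyte factor Sox10 (-3.49) and the insulin receptor substrate Irs4 (-2.98) completed the 10 lowest. The 10 highest began with Adamtsl3 (3.20, from 8 and 6 wild-type counts, chromosome 7, 82335694 to 82614450), the potassium channel Kcna1 (2.94, from 8 and 3 wild-type counts), Neurod4 (2.40) and the hyaluronan-binding protein Cemip (2.33). They went on with Slc17a7 (2.07), the dopamine-signalling phosphoprotein Ppp1r1b (1.74), the kinase Alpk1 (1.66), the manganese transporter Slc30a10 (1.64), the metalloprotease Adamts18 (1.63) and Etl4 (1.60). These values are log2 fold changes past the threshold in edgeR with the library labelled wild type 2, whose Eed count went against its label, in the wild-type group. All 20 genes lost their calls when EedcKO 3 was left out. They kept their direction with an unadjusted edgeR p under 0.05, but neither is a separate check. The genes were picked for groups that do not overlap, so the direction could not reverse, and that fit shares its libraries with the main fit.

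Of 25 tested genes of the ventral telencephalon, 7 fell, none rose, and 18 passed when p was adjusted over the list alone. Beside Shh and Lhx8, the vesicular GABA transporter Slc32a1 fell from 87.8 ± 18.9 to 41.9 ± 5.55 CPM (log2 fold change -1.07, SE 0.16, edgeR adjusted p = 0.0210). The interneuron transcription factor Sp9 fell from 131 ± 20.6 to 66.7 ± 8.63 CPM (-0.97, SE 0.14, edgeR adjusted p = 0.0165). Of 15 tested diencephalon genes 3 fell and none rose (5 adjusted over the list alone). They were Otp, the transcription factor Fezf1 (-2.71, SE 0.27, edgeR adjusted p = 0.00850) and Barhl2 (-0.79, SE 0.15, edgeR adjusted p = 0.0361). Of 12 tested Cajal-Retzius genes 5 fell and none rose (7 adjusted over the list alone). Among them were Car10 (-2.69), the transcription factors Lhx5 (-1.82) and Lhx1 (-1.68), and the calcium channel subunit Cacna2d2 (-0.67). Decreases were more frequent than among all tested genes in the ventral (Fisher's exact test, one-sided, adjusted p = 1.67e-05), diencephalon (0.0377) and Cajal-Retzius lists (4.51e-05). Camera with a preset correlation of 0.01 put these lists lower with adjusted p = 2.02e-19, 2.64e-05 and 7.32e-10, and none held with an estimated correlation (adjusted p = 0.362 for each of these lists). Ventral, diencephalon and Cajal-Retzius decreases numbered 9, 6 and 4 without the library labelled wild type 2, whose Eed count went against its label. They numbered 6, 5 and 6 without wild type 1, 11, 1 and 5 without EedcKO 1, 1, 2 and 2 without EedcKO 2, and 0, 0 and 0 without EedcKO 3.

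**Figure D2:**
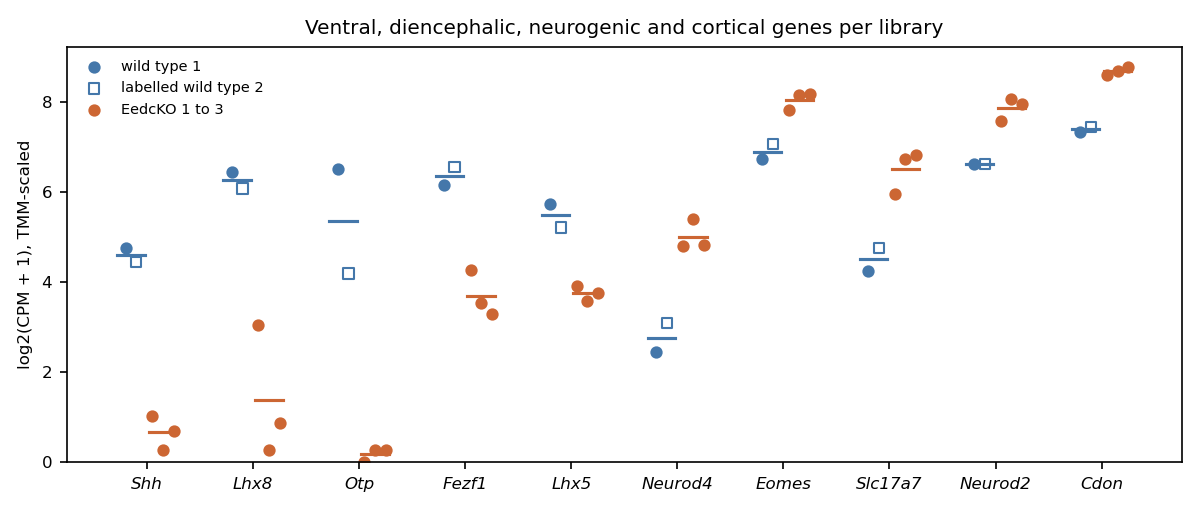
Expression of 10 named genes per library as log2(CPM + 1) on the vertical axis, with blue for libraries labelled wild type (open square, the library labelled wild type 2), orange for EedcKO and a line at each group's mean. Shh, Lhx8, Otp, Fezf1 and Lhx5 were lower and Neurod4, Eomes, Slc17a7, Neurod2 and Cdon higher in all 3 EedcKO libraries than in either library labelled wild type, although the Eed count of wild type 2 went against its label.

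Of 17 tested genes of cortical excitatory neurons 8 rose and 1 fell (11 adjusted over the list alone). The largest change was in Slc17a7 (log2 fold change 2.07, SE 0.30, edgeR adjusted p = 0.0216). The neuronal transcription factor Neurod2 rose from 97.1 ± 0.147 to 235 ± 39.8 CPM (1.28) and Neurod6 from 92.4 ± 3.25 to 215 ± 22.2 CPM (1.22). The gene of the list that fell was Tle4 (-0.61), a corepressor of deep-layer neurons, named here after its value was seen. Of 16 tested genes of intermediate progenitors and neurogenesis 5 rose and none fell (8 adjusted over the list alone). Among them were Neurod4, the proneural factor Neurog1 (1.48), the somatostatin receptor Sstr2 (1.45) and the intermediate progenitor factor Eomes (1.16, from 119 ± 20.2 to 267 ± 36.2 CPM). Of 24 tested genes of telencephalic radial glia 3 rose and none fell (6 adjusted over the list alone). They were Gli3, a repressor of hedgehog targets (0.78), the glutamate transporter Slc1a3 (0.68) and the progenitor factor Pax6 (0.65). Increases were more frequent than among all tested genes in the cortical (Fisher's exact test, one-sided, adjusted p = 1.73e-10), neurogenic (1.56e-05) and radial glia lists (0.0220). Camera gave adjusted p = 9.53e-12, 3.56e-11 and 1.28e-06 for these lists, against an adjusted p = 0.362 for each with an estimated correlation. Cortical, neurogenic and radial glia increases numbered 6, 8 and 8 without the library labelled wild type 2, whose Eed count went against its label. They numbered 9, 5 and 4 without wild type 1, 6, 6 and 2 without EedcKO 1, 2, 1 and 0 without EedcKO 2, and 0, 0 and 0 without EedcKO 3.

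Members of the sonic hedgehog pathway moved in both directions. Of 10 tested genes 4 rose and 1 fell (8 adjusted over the list alone, 4 higher and 4 lower). The hedgehog co-receptor Cdon rose from 167 ± 9.48 to 413 ± 25.5 CPM (log2 fold change 1.30, edgeR adjusted p = 0.00455). The co-receptors Boc (0.98) and Gas1 (0.88) rose, as did the effector Gli2 (0.56), named here after its value was seen. Gli1, a transcriptional target of the pathway, fell (-1.93, from 28.9 ± 6.30 to 7.54 ± 3.70 CPM, edgeR adjusted p = 0.0412). The list's median log2 fold change was 0.01 and its mean -0.27, while camera put it higher (adjusted p = 0.0471, or adjusted p = 0.447 with an estimated correlation). Pan-neuronal genes had 3 decreases of 21 tested (7 adjusted over the list alone). They were in the neurofilament Nefl (-1.14), the synaptic vesicle protein Syt1 (-0.74) and the microtubule protein Mapt (-0.53). The list's camera adjusted p was 5.68e-05, or adjusted p = 0.633 with an estimated correlation. Its sum stood highest in wild type 1 (6373 CPM), against 5257.5 in the library labelled wild type 2 and 4890 to 5185 in EedcKO. In glial genes the transcription factors Nfib (0.77) and Nfia (0.76) rose and Sox10 fell, of 18 tested (6 adjusted over the list alone). Among 26 tested imprinted genes Plagl1 rose (0.53), and Dlk1 (-1.55, from 165 ± 45.1 to 56.2 ± 8.09 CPM) and Ddc (-2.47) fell (14 adjusted over the list alone). Camera put the imprinted list lower (adjusted p = 3.47e-05, or adjusted p = 0.362 with an estimated correlation). That list summed to 5206 CPM in wild type 1, 4257.5 in the library labelled wild type 2 and 3472 to 3959 in EedcKO. The wild-type group of these values includes the library labelled wild type 2, whose Eed count went against its label. Without that library hedgehog calls numbered 7 and pan-neuronal decreases 7. They numbered 3 and 3 without wild type 1, 4 and 1 without EedcKO 1, 2 and 0 without EedcKO 2, and 0 and 0 without EedcKO 3.

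None of the 6 PRC2 core genes passed the test. The log2 fold changes beside Eed were 0.15 for the methyltransferase Ezh2, -0.19 for Ezh1, 0.30 for Suz12, 0.04 for Rbbp4 and 0.03 for Rbbp7 (edgeR adjusted p between 0.163 and 0.897). None of 6 accessory genes passed (Aebp2 0.18, Phf19 0.31), and of 19 genes of Polycomb repressive complex 1, Pcgf5 (0.82) and Bmi1 (0.50) rose. Only 2 of the 39 HOX genes had enough counts to be tested, and neither passed (Hoxd8 1.17, edgeR adjusted p = 0.499; Hoxb8 0.99, edgeR adjusted p = 0.702). Of 16 HOX genes with a count in all 3 EedcKO libraries, 1 had a count in wild type 1 and 15 in the library labelled wild type 2. The midbrain, hindbrain and spinal cord list had 1 decrease of 9 tested genes, Mab21l2 (-1.88; 3 adjusted over the list alone). Its camera adjusted p was 0.0471, or adjusted p = 0.447 with an estimated correlation. None of 18 tested mesoderm and endoderm factors passed (Eya4 0.86, Tbx18 1.04). Cyclin-dependent kinase inhibitors had no call of 6 tested (Cdkn1c -0.41, Cdkn2c 0.62; 3 adjusted over the list alone). These values too are drawn against a group with the library labelled wild type 2, whose Eed count went against its label, and no listed gene passed without EedcKO 3.

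The remaining lists held few or no calls against the same wild-type group, in which 1 library's Eed count went against its label, and none without EedcKO 3. The cell cycle list had 1 increase of 32 tested genes, the mitotic survivin Birc5 (0.42; 12 adjusted over the list alone), and a camera adjusted p = 4.55e-10, or adjusted p = 0.362 with an estimated correlation. Ndrg1 (1.26) rose among 16 hypoxia genes, and Sfrp1 (0.79) among 17 WNT genes (1 and 1 adjusted over the list alone). Of 21 BMP and TGF-beta genes 1 rose, Id2 (0.83), and 1 fell (2 adjusted over the list alone). There were no calls among p53 targets (Plk2 -0.43, Ckap2 0.36; 3 adjusted over the list alone) and SOXC genes (Sox12 -0.06, Sox4 0.03). Nor were there any in the immediate early (Arc -0.86, Egr3 -1.60) and integrated stress response lists (Shmt2 0.33, Psat1 0.18). The cortical hem and choroid plexus list had no call of 21 tested genes (Otx2 -1.47, Bmp4 -1.45). Camera put it lower with an adjusted p = 0.00597, or adjusted p = 0.828 with an estimated correlation. Its sum was 1498 CPM in the library labelled wild type 2 against 527 in wild type 1 and 369 to 778 in EedcKO, so by these sums the lower direction rests on that library. In all, 13 of 35 lists passed with camera and a preset correlation, 0 of these with an estimated correlation, and fry's directional test gave no adjusted p under 0.0741. Fry's mixed test, which takes changes in either direction, passed some lists and not others. Its adjusted p was 0.00149 for p53 targets and 0.00322 for the cell cycle, radial glia and diencephalon lists. It was 0.405 for the cortical hem and choroid plexus list. Medians and means differed in sign in the hedgehog, PRC2 core, p53 target, glial and meninges lists. Camera's direction differed from both in the mesoderm and endoderm and the stress response lists. Of these lists the hedgehog list alone passed camera with a preset correlation.

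**Figure D3:**
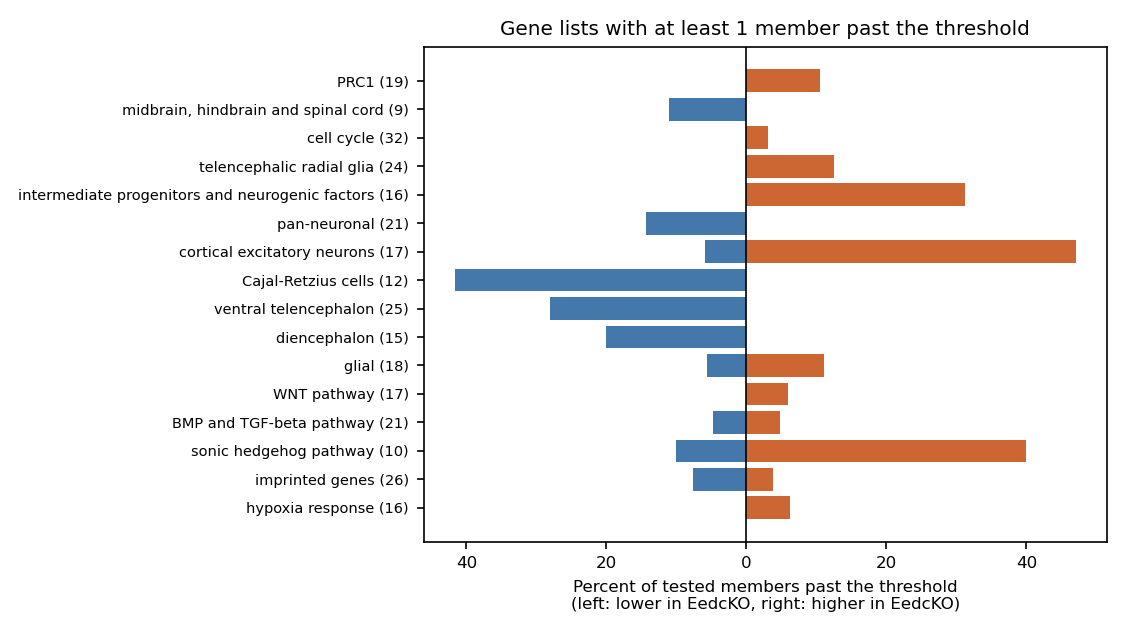
Percent of the tested members of each gene list that were lower (blue, left) or higher (orange, right) in EedcKO past an edgeR false discovery rate of 0.05, with the number of tested members in parentheses after the list's name. Cortical excitatory neurons had 8 increases of 17 and Cajal-Retzius cells 5 decreases of 12, with the library labelled wild type 2, whose Eed count went against its label, in the wild-type group.

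Markers of some other tissues set the library labelled wild type 2 apart. Its epithelium markers summed to 247 CPM, against 26.8 in wild type 1 and 13.5 to 25.3 in EedcKO. Its skeletal and cardiac muscle markers summed to 108 CPM, against 14.5 in wild type 1 and 11.4 to 16.9 in EedcKO. Its erythroid markers summed to 672 CPM, against 265 in wild type 1 and 257 to 451 in EedcKO. Other lists did not follow this: meninges and mesenchyme markers summed highest in EedcKO 1 (1088 CPM, against 827 in the library labelled wild type 2 and 508 in wild type 1). Endothelial markers summed lowest in the library labelled wild type 2 (315 CPM, against 327.5 to 452 in the other libraries). No gene of a cell type list passed the threshold, so the following log2 fold changes are values only. They were -0.61 for Hbb-bt and -0.17 for Hbb-y of the erythroid list, and 0.28 for Flt1 and 0.17 for Plvap of the endothelial list. Pericyte markers had -0.75 for Zic1 and 0.31 for Notch3 (1 adjusted over the list alone), and macrophage markers -0.55 for both C1qc and Trem2. Meningeal Foxd1 had -0.998 and Prrx1 0.73. Neural crest Tfap2b had -1.25 and Ngfr -0.78 (3 adjusted over the list alone), and pigment cell Dct had 1.36 and Pmel -0.79. Muscle Tnnt1 had -2.08 and Actc1 -2.10 (1 adjusted over the list alone). Epithelial Krt8 had -2.93 and Cdh1 -2.79 (2 adjusted over the list alone). The epithelium list passed camera (adjusted p = 0.00259, or adjusted p = 0.633 with an estimated correlation). The first principal component of log2 CPM (47.7% of the variance) separated the groups. It placed wild type 1 at -26.0, the library labelled wild type 2 at -37.9 and the EedcKO libraries between 9.5 and 34.5. The second (26.7%) placed wild type 1 at 35.9 and the library labelled wild type 2 at -27.4, with the EedcKO libraries between -8.49 and 2.62.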

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

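The tests of carried-over reads, of outside tissue, of the listed genes in wild type 2, of its position on all 31 and all 882 genes, of unequal dissection and of other splits were chosen after the results they bear on had been seen; those of a label exchange over all genes, of embryo sex and of transcript length were also added after the main fit and values per library had been seen, but their bounds were written before their own values were computed.

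Rows without a gene symbol lay outside the comparison, and 8 of 2095 such rows tested passed an edgeR false discovery rate of 0.05 (4 higher and 4 lower in EedcKO), while 198 had an unadjusted p under 0.05. They carry no name, so no explanation was tested.

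The library labelled wild type 2 had Eed and HOX counts at the EedcKO level, and its Eed CPM was 56.8% of that of wild type 1. The values argue against reads carried over from the EedcKO libraries. Its Y-linked counts were 0.78% of the male EedcKO mean (upper 95% binomial limit 1.36%). Its HOX counts were 109% of the male EedcKO mean (91.3% to 129%), and also exceeded those of the female EedcKO 1. Dilution by outside tissue as the reason for its Eed count is argued against by its radial glia genes, which summed to 98.2% of wild type 1. Against wild type 1 its other forebrain lists went both ways. Its ventral genes summed to 2629 against 3407 CPM, its pan-neuronal genes to 5257.5 against 6373 and its cortical genes to 1679 against 1893. Its neurogenic genes summed to 1424 against 1393 CPM and its diencephalic genes to 547 against 540.5. On 28 of 31 listed forebrain genes called without it, those the main fit also tested, its median position was 0.262 (quartiles 0.15 and 0.326, with wild type 1 at 0 and the EedcKO mean at 1; 0.282 on all 31, quartiles 0.173 and 0.393), which argues against an exchange with an embryo as affected as the EedcKO libraries. Over all genes called without it and tested in the main fit, its median was 0.402 (quartiles 0.164 and 0.713), between the bounds set for it. With the called genes that the main fit did not test, it was 0.41. These genes were picked for the distance of wild type 1 from EedcKO, and wild type 1 was also set at 0. A correctly labelled second wild type would therefore be drawn above 0 as well, so this median cannot decide. A mislabelled or partly recombined but less affected embryo may remain open. Tissue from outside the forebrain remains a candidate source of the HOX counts in the library labelled wild type 2. Its epithelium markers summed to 247 CPM, above every other library. Its midbrain, hindbrain and spinal cord list summed to 116 CPM, against 82.6 in wild type 1 and 44.1 to 55.3 in EedcKO. Members of that list went both ways against wild type 1 (Pax7 48 against 4 counts, Prdm12 74 against 134). EedcKO libraries with epithelium markers near those of wild type 1 had HOX counts as well, which cannot decide their source in the library labelled wild type 2.

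Of the listed genes, 7 of 25 ventral and 3 of 15 diencephalic ones were called lower in EedcKO, and 5 of 16 neurogenic and 8 of 17 cortical ones higher (1 cortical gene lower), with 2 of the 3 EedcKO libraries male and no male wild type. As lists none passed camera with an estimated correlation (adjusted p = 0.362 for each). Embryo sex as the whole cause is argued against by the female EedcKO 1, whose median position on 262 genes called without it was 0.757 (quartiles 0.597 and 0.907, with the wild-type mean at 0 and male EedcKO at 1), and 0.652 on 25 of these that are listed ventral, diencephalic, neurogenic or cortical genes. With sex as a covariate the calls ended. No wild type was male, so the sex term takes up EedcKO 2 and 3, and the genotype effect compares EedcKO 1 alone with the wild type. Fold changes in that fit are therefore those of EedcKO 1. They were smaller, with larger standard errors and 2 residual degrees of freedom in place of 3, and which of these ended the calls was not tested. The 24 listed calls had a median size of 1.18 (median SE 0.16) before and 0.98 (median SE 0.19) after, with no edgeR adjusted p under 0.135. Transcript length is argued against, since 100% of those 24 calls held their direction and at least 50% of their log2 fold change once a length trend was removed. The deletion of Eed and an unequal share of ventral and diencephalic tissue in the dissected forebrains cannot be told apart: the median log2 fold change of the ventral list was -0.97, with members from -5.19 (Shh) to 0.40 (Sp8) and cortical ones from -0.61 (Tle4) to 2.07 (Slc17a7), so the members did not share 1 factor, but a lost part of the ventral tissue would not move them alike either, and no record of the dissection was used here, so the genotype may be the cause only as a hypothesis.

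The real grouping gave 448 genes past the threshold and the highest of the other splits of the 5 libraries into 2 and 3 gave 6, for EedcKO 2 and 3 against the rest. Of 10 splits 1, the real grouping, gave as many genes; with 10 splits the share is never under 0.1, so it cannot fall under 0.05.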

How the results depend on the processing

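The length and GC corrections and the fit of female libraries were chosen after the results were seen; all other settings were planned. Of 448 calls 145 were higher and 303 lower. With library size alone 675 genes passed (230 higher), with DESeq2 679 (260 higher), with no count filter 228 were higher, with the length trend removed 752 passed (241 higher, 511 lower), and with the GC trend removed 241 were higher. Fewer passed with limma-trend on TPM: 203 at a pseudocount of 1 (68 higher, 135 lower), 152 at 0.1 (51 and 101) and 42 with no filter on low values (9 and 33). Against a 1.5-fold change 33 passed (7 higher, 26 lower). With edgeR the sex covariate gave 0 (0 higher, 0 lower), and so did the female libraries alone, with 902 genes at an unadjusted p under 0.05; DESeq2 called 55 and 13 there and limma-voom 0 and 0. The sex covariate and the female libraries both compare EedcKO 1 alone with the wild type, so they are not separate checks. The cause of the differences between settings was not tested. Counts with 1 library left out ranged from 0 to 1012, higher calls from 0 to 433 and lower calls from 0 to 587. The share of higher calls was 28.9% to 38.3% in the other fits with calls on all 5 libraries, except 21.4% with unfiltered TPM and 7 of 33 against a 1.5-fold change. In fits with calls and 1 library left out it ranged from 25% without EedcKO 2 to 42.8% without wild type 1. RLE factors, limma-voom, robust estimation off, the 1 CPM filter and leaving out globin genes gave 398 to 471 calls.

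The replicate block gave 0 genes with edgeR (0 higher, 0 lower; 2169 at an unadjusted p under 0.05), 0 with limma-voom and 120 with DESeq2, with 1 residual degree of freedom. Same-numbered samples correlated at -0.0412 and 0.13 across genes in their deviations, and with 2 shared numbers the pairing was not taken as given.

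The Eed log2 fold change ranged from -0.43 to -0.34 on all 5 libraries or the female libraries, and from -0.75 to 0.043 with 1 library left out. No HOX gene was called higher in the fits compared for it, which leave out the 1.5-fold test and the DESeq2 and limma-voom fits of the designs where edgeR gave 0. Of 35 lists 13 passed with camera, 0 with an estimated correlation and 14 with cameraPR. Ventral, diencephalon and Cajal-Retzius decreases numbered 15, 4 and 7 with DESeq2, 5, 2 and 3 with TPM at a pseudocount of 1, 3, 2 and 2 at 0.1, 1, 0 and 0 with unfiltered TPM, and 0 with the block or the sex covariate. Cortical, neurogenic and radial glia increases numbered 9, 8 and 4 with DESeq2, 5, 5 and 3 with TPM at a pseudocount of 1, 4, 3 and 2 at 0.1, 1, 0 and 0 with unfiltered TPM, and 0 with the block or the sex covariate. List members past the threshold numbered 54 over all genes tested and 124 when adjusted over the list alone. No fit compared reversed the direction of a named gene past the threshold. The groups of these genes did not overlap, so fits that left out libraries or rested on EedcKO 1 alone could not have reversed it. Of 57 named genes past the threshold 57 lost their calls with the block, the sex covariate, the female libraries or without EedcKO 3, 53 with unfiltered TPM, 25 and 16 with TPM at pseudocounts of 0.1 and 1, 9 with limma-voom, 40 without EedcKO 2, 17 without EedcKO 1, 7 without wild type 1, 7 without the library labelled wild type 2 and at most 4 in any other fit compared.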

Other observations

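The medial ganglionic eminence and hypothalamus factor Nkx2-1, outside the rule for named genes and chosen after its values were seen, differed among the EedcKO libraries. It had 182 and 147 CPM in wild type 1 and the library labelled wild type 2, 69.1 in EedcKO 1, and 1.45 and 1.23 in EedcKO 2 and 3 (log2 fold change -2.79, SE 1.35, edgeR adjusted p = 0.406). Lhx6, a transcription factor of ventral interneurons chosen in the same way, had 187 and 177 CPM beside 70.6, 35.6 and 21.9 (log2 fold change -2.09, edgeR adjusted p = 0.0695). Ptch1, a hedgehog receptor and target, had 223 and 139 CPM beside 102, 81.5 and 65.6 (log2 fold change -1.12, edgeR adjusted p = 0.0572). EedcKO 1 was the female EedcKO library, and whether sex, dissection or the extent of deletion accounts for its place was not tested for these genes.

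Cdkn2a, a Polycomb target that encodes cell cycle inhibitors, was chosen after its values were seen and set wild type 1 apart as the HOX genes did, with 0 counts in wild type 1, 20 in the library labelled wild type 2, and 17, 52 and 23 in EedcKO 1, 2 and 3. The log2 fold change was 1.61 (edgeR adjusted p = 0.487), which did not pass. HOX genes of paralog groups 9 to 13 gave 1 of the 2 HOX counts in wild type 1, 31 of 134 in the library labelled wild type 2, and 18 of 85, 70 of 184 and 22 of 62 in the EedcKO libraries. Of 28 HOX genes with a count in the library labelled wild type 2, 26 had a count in an EedcKO library.

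Krt5, a keratin of stratified epithelium chosen after its values were seen, had 428 counts in the library labelled wild type 2 and 0 in wild type 1, and 20, 1 and 0 in the EedcKO libraries. Across genes, which are not independent replicates, the log2 ratio of wild type 1 to the library labelled wild type 2 correlated with gene length (Spearman 0.388), against 0.0897 for the log2 fold change between the groups. The Eed log2 ratio of wild type 1 to the library labelled wild type 2 was 0.81, above 99.7% of 1268 genes of similar level and length. Of 442 calls with a known chromosome, 18 lay on the X chromosome and 0 on the Y. The edgeR fit tested 479 genes on the X chromosome.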
